A study of Homo sapiens with 24 samples.

How the data were processed

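Gene expression was measured by sequencing libraries of messenger RNA from IMR90 cells, an established line of human fetal lung fibroblasts, that carry a mutant RAS fused to an estrogen receptor. In these cells 4-hydroxytamoxifen (4-OHT) switches the RAS protein on. Per the labels, 8 libraries came from untreated cells (control), 8 from cells given 100 nM 4-OHT for 6 days (RAS-induced senescence, RIS) and 8 from cells given 100 uM etoposide, a topoisomerase II poison that breaks DNA, for 2 days and cultured for 5 days more (DNA damage-induced senescence, DDIS). The series' design text calls the 8 libraries of a group biological replicates, and the labels do not say which cultures or days they came from, so the p-values measure the spread between these libraries. Total RNA was taken with a miRNeasy kit and made into libraries with the TruSeq RNA kit, per the labels' protocols.

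The authors deposited 1 file of raw read counts per gene for each library, 24 files in all, with no normalization. Per the submitters' processing notes, the tools were TopHat2 version 2.0.4, HTSeq version 0.5.3p9 and DESeq version 1.10.1, with the GRCh37 build of the human genome. Which annotation release, which strand setting and which role each tool had are not given in the sources used here. Each file lists 54127 Ensembl gene IDs and 5 summary lines that name no gene. Reads outside annotated genes made up 4.82% to 9.06% of all lines' counts, reads of ambiguous genes 4.92% to 6.08% and reads aligned to several places 8.56% to 10.8%. These lines stayed out of library sizes and tests. Because the strand setting is not given, genes that overlap a gene on the other strand could share reads with it.

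Gene IDs were matched to symbols, positions and biotypes in a GRCh37 annotation (GENCODE lifted to GRCh37), which held 47098 of the 54127 IDs, 19012 of them protein coding. The exonic GC content and length of each gene were computed from the GRCh37 genome. Gene counts summed to 4464328 to 8283143 per library, so that 1 count is worth 0.12 to 0.22 CPM, the count scaled to a library of 1e+06.

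Differential expression was tested with edgeR version 4.0.16 in R version 4.3.3 (glmQLFit and glmQLFTest, robust, TMM scaling), with the 24 libraries in 1 fit, a mean per group and no block. Genes were kept by filterByExpr with its minimum count of 10 and total of 15, which left 12596 genes and removed 0.198% to 0.523% of the counts of a library. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested). Log2 fold changes are given with their standard errors (SE), and expression as mean CPM ± SD over the 8 libraries of a group. The biological coefficient of variation was 13.2%. Gene lists (16, with the tests and the rule for named genes written before the data were examined) were tested with camera of limma version 3.58.1 on log2 CPM with a prior count of 2 and the preset correlation of 0.01, two-sided, adjusted over the 16 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Measures of single libraries were compared with exact two-sided permutation tests, and correlations over the 8 libraries of a group with exact permutation of the pairings.

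The genes named were set by that rule. They are 16 anchor genes in every comparison, and the 4 called protein-coding genes with the highest and the 4 with the lowest log2 fold change among those with a mean log2 CPM of at least 2 and no overlap between the groups. They also include the called members of each list with the largest change, 2 per comparison with control and 1 in RIS against DDIS, among members with a mean log2 CPM of at least 1. Genes named outside this rule were chosen after their values were seen, and the text says so where they stand. Some results of this rule are not reported here.

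The fit was tested on simulated counts for the 12596 genes, with 200 genes changed by 1.5-, 2- or 4-fold in the first group of a comparison. For RIS against control it recovered 70.1% of the genes changed 1.5-fold, 94.0% of those changed 2-fold and 98.5% of those changed 4-fold, and 4.37% of the calls were on unchanged genes. For DDIS against control it recovered 71.2%, 92.5% and 95.5% in the same order, with 4.44% of the calls on unchanged genes, and for RIS against DDIS 85.1%, 97.0% and 97.0%, with 1.59%. The real comparisons called far more genes than the 200 changed here, namely 7821, 7552 and 6745 of 12596 in the same order. Scaling with so many changed genes was not tested. The recovery and the shares of calls on unchanged genes therefore hold for the simulated counts and may not carry over to the real ones. No pair of libraries of a group agreed within counting noise (chi-square per degree of freedom of 1.53 to 29.3 over 84 pairs).

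The alternatives were a block for the replicate number, a block for the letter in the deposited files' codes (A, B or C, with 3, 2 and 3 libraries per group), each letter alone, 2 other scalings, other count filters, DESeq2 version 1.42.0, limma voom, only the groups compared, a 2-fold minimum, and leaving out each library. A correction for GC content, fits without doubtful libraries and 15 gene families were added after the data were seen. Other splits of the libraries, 100 per comparison with the real one included, were fitted with the main settings. Counting intervals and floors cover counting error only. The other intervals, in the closing sections, came from 2000 resamples of genes, so they hold no spread between libraries. Markers of other cell types were looked up in all 24 libraries. CCL3, CCL5, MMP12 and the endothelial marker PECAM1 had no matching ID and were not analysed here. The count filter also removed members of several lists, such as 9 of 30 interferon-stimulated genes, so counts per list cover tested members only.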

Results

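Messenger RNA was measured by sequencing in IMR90 ER:RAS cells, fetal lung fibroblasts in which 4-OHT switches on a mutant RAS, the signalling protein whose excess activity drives many fibroblasts into senescence. Senescence is a lasting arrest of the cell cycle, and senescent cells secrete cytokines, proteases and matrix proteins, together called the secretome. The design held 8 control libraries of untreated cells, 8 RIS libraries (RAS-induced senescence) and 8 DDIS libraries (senescence after etoposide). Gene counts summed to 5323315 to 7182521 per library in control, 4464328 to 8283143 in RIS and 4724613 to 6906373 in DDIS. Depth did not differ detectably between the groups (exact two-sided permutation p = 0.805 for RIS against control and 0.752 for DDIS against control, n = 8 and 8). The first principal component held 57.2% of the variance of log2 CPM and the second 19.2%. The title of the series concerns NOTCH1 and a change between secretomes, so the NOTCH, TGF-beta and inflammatory genes are described in each comparison.

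The first comparison asks what 6 days of 4-OHT, which switches RAS on, did to expression. The design held no cells without the construct that were given 4-OHT. Effects of 4-OHT itself therefore cannot be told apart from those of active RAS. In RIS the inflammatory cytokine gene IL1B (ENSG00000125538, GRCh37 chromosome 2, 113587328 to 113594393, minus strand) rose from 7.12 ± 1.89 CPM in control to 5502 ± 427 CPM (SD, n = 8 each), a log2 fold change of 9.59 (SE 0.212, adjusted p = 4.09e-23). MMP3, which encodes the matrix protease stromelysin (ENSG00000149968, chromosome 11, 102706532 to 102714340, minus strand), rose from 7.67 ± 1.06 to 2653 ± 292 CPM (log2 fold change 8.43, SE 0.126, adjusted p = 1.31e-28). The nuclear lamina gene LMNB1 (ENSG00000113368, chromosome 5, 126112315 to 126172712, plus strand) fell from 51.8 ± 4.42 to 4.67 ± 0.953 CPM (log2 fold change -3.48, SE 0.138), and the proliferation marker MKI67 fell from 139.7 ± 18.5 to 9.19 ± 2.04 CPM (log2 fold change -3.91, SE 0.23). The cyclin-dependent kinase inhibitor gene CDKN1A (ENSG00000124762, chromosome 6, 36644237 to 36655114, plus strand) rose from 522 ± 48.9 to 1969 ± 234 CPM (log2 fold change 1.91, SE 0.0895). Of 12596 genes tested, 7821 were called, 3857 higher and 3964 lower in RIS, and 2174 of them changed 2-fold or more (976 higher, 1198 lower). In 32.7% of the genes tested the 8 libraries of one group all lay above the 8 of the other, which chance gives for 0.0155%. Within the letters A, B and C of the file codes alone, 5090, 7082 and 4477 genes were called.

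Genes tied to the secretome formed 2 of the lists, an inflammatory list and a list of proteases and inhibitors. Of 24 inflammatory genes tested, 22 rose in RIS and 2 fell (median log2 fold change 5.13, camera adjusted p = 2.25e-15). Beside cytokines and chemokines this list held ICAM1, IL13RA2, TNFAIP3, NFKBIA and PTGS2, which are neither. CXCL8, a neutrophil chemokine, rose by 5.20 on the log2 scale (SE 0.19), IL6 by 3.28 (SE 0.219) and IL1A by 6.48 (SE 0.215). CSF3, the granulocyte growth factor gene (ENSG00000108342, chromosome 17, 38171614 to 38174066, plus strand), had 11724 counts in RIS and 3 in control, a ratio of 3961 with a 95% counting interval of 1355 to 19209. The members that fell, named after their values were seen, were CCL2 (log2 fold change -1.69, SE 0.19) and CSF1 (-0.84), both growth or attraction signals for monocytes. Of 22 genes in the list of proteases and inhibitors, which also held PLAUR and STC1, 17 rose and 4 fell (median 1.36, adjusted p = 1.26e-08). Among those that rose was SERPINB2, an inhibitor of plasminogen activators, from 15.1 ± 1.72 to 984.5 ± 71.7 CPM. Of 19 genes in the list of NF-kB, C/EBP and AP-1 transcription factors, which also held IRF1, 13 rose and 5 fell (median 0.68, adjusted p = 0.0117). The C/EBP factor CEBPB rose by 1.40 (SE 0.0879) and the AP-1 factor FOSB by 2.64 (SE 0.301). This list lost its call with an estimated correlation (adjusted p = 0.245, with a range of 1.11e-07 to 0.245 over 9 alternatives) and with the GC correction (adjusted p = 0.124).

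Genes of the cell cycle fell in RIS. All 39 tested genes of S phase and mitosis fell (median log2 fold change -3.12, adjusted p = 5.61e-21), with MYBL2 at -4.24 (SE 0.268) and TTK at -4.06 (SE 0.362). Of 24 genes of homologous recombination and fork repair, 23 fell (median -2.53, adjusted p = 6.24e-11), such as BARD1 (-3.68, SE 0.16) and BRIP1 (-3.56, SE 0.186). The mean log2 CPM of this list was 1.04 in RIS replicate 8 and 1.55 to 1.88 in the other 7 RIS libraries. Among 30 p53 target genes 27 rose and 1 fell (median 0.69, adjusted p = 9.3e-09), led by GDF15, a stress cytokine of the TGF-beta family, from 30.6 ± 3.33 to 711.8 ± 118 CPM, and CYFIP2 (1.96, SE 0.145). CDKN2B, which encodes the inhibitor p15, rose from 16.1 ± 2.04 to 100.8 ± 15.7 CPM (log2 fold change 2.65, SE 0.117). CDKN2A rose from 20.8 ± 2.03 to 33.7 ± 4.69 CPM (0.69, SE 0.117). Its counts do not separate the p16 and p14ARF transcripts, and 15.3% of the gene's exonic length overlaps a gene on the other strand. Senescence hallmark genes, a list with members of both expected directions, held 12 that rose and 10 that fell, among them HMGB2 (-3.46, SE 0.214). Its median (0.11) and mean (-0.12) differed in sign and the list was not called (adjusted p = 0.469).

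NOTCH1 (ENSG00000148400, chromosome 9, 139388885 to 139440500, minus strand), the receptor named by the title, rose in RIS from 41.2 ± 4.1 to 74.4 ± 6.34 CPM (log2 fold change 0.86, SE 0.0821, adjusted p = 2.8e-10). Of 18 Notch receptors, ligands and targets tested, 9 rose and 2 fell (median 0.45, adjusted p = 0.0223). The list held 27 genes, and the count filter removed 9, among them the targets HES5, HEY2, HEYL and NRARP and the ligands DLL1 and DLL3. The Notch coactivator MAML3 rose by 1.64 (SE 0.139) and the Notch target HEY1 by 1.34 (SE 0.13), whereas the receptor genes NOTCH2 (-0.53) and NOTCH3 (-1.13), named after their values were seen, fell, and the ligand JAG1 did not pass the test (0.06, SE 0.13, adjusted p = 0.731). With the GC correction, added after the data were seen, the Notch list was no longer called (adjusted p = 0.238, range 8.05e-14 to 0.238 over 9 alternatives). Of 27 TGF-beta ligands and targets, 7 rose and 17 fell (median -0.44, adjusted p = 0.00293), a call lost with an estimated correlation (adjusted p = 0.181, range 8.05e-14 to 0.181 over 9 alternatives). ACTA2, smooth muscle actin, fell from 485.6 ± 70.6 to 32.3 ± 4.36 CPM and TAGLN, transgelin, from 1247 ± 94 to 143 ± 23.6 CPM. These genes overlap genes on the other strand over 35.9% and 34.1% of their exonic length, and the counting strand is not given. The ligand gene TGFB1 itself fell by 0.29 (SE 0.1, adjusted p = 0.015), a call that was lost without Control replicate 7 (log2 fold change -0.22, adjusted p = 0.0528, range 5.71e-08 to 0.0528 over 33 alternatives). Of 30 collagen and matrix genes, 3 rose and 25 fell (median -1.36, adjusted p = 4.64e-09), for example elastin, ELN (-3.19, SE 0.155), and FBLN1 (-2.48, SE 0.119). This call was lost with an estimated correlation (adjusted p = 0.105, range 1.22e-18 to 0.105 over 9 alternatives).

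Genes that respond to RAS and ERK signalling rose, 21 of 27 with 2 lower (median 1.11, adjusted p = 2.94e-10), led by the ERK phosphatase gene DUSP4 (5.55, SE 0.135) and the EGF receptor ligand AREG, from 0.401 ± 0.348 to 17.2 ± 3.35 CPM. HRAS (ENSG00000174775, chromosome 11, 532242 to 537321, minus strand) rose from 2210.3 ± 119 to 3574 ± 385 CPM (0.69, SE 0.0721). The labels do not name the RAS gene of the construct, whose transcripts would be counted on its human gene where the sequences match. NRAS fell by 0.51 (SE 0.0707). Lysosome and autophagy genes were higher for 21 of 26 and lower for 2 (median 0.65, adjusted p = 3.48e-07), such as the sialidase gene NEU1 (1.27, SE 0.0817). Their mean log2 CPM was 7.27 in RIS replicate 8 and 6.94 to 7.04 in the other 7 RIS libraries. The call was lost with an estimated correlation (adjusted p = 0.115, range 5.81e-15 to 0.115 over 9 alternatives). Glycolysis and hypoxia genes were higher for 18 of 23 and lower for 1 (median 0.62, adjusted p = 8.03e-06), such as NDRG1 (2.39, SE 0.0913) and VEGFA (2.29, SE 0.1). This list lost its call too (adjusted p = 0.181 with an estimated correlation, range 2.74e-11 to 0.181). Not called were the interferon-stimulated genes (1 higher, 10 lower of 21, adjusted p = 0.0553, with OAS3 at -1.77 and CXCL10 at 1.09) and the cholesterol synthesis genes (3 higher, 14 lower of 23, adjusted p = 0.0731, with TM7SF2 at 1.24 and ACAT2, which has an overlap of 17.2% on the other strand, at -1.21). Also not called were the genes of unfolded protein and amino acid stress (13 higher, 4 lower of 21, adjusted p = 0.221). The interferon list was called with the replicate block (adjusted p = 0.0462) and without Control replicate 2 (0.0481), 4 (0.0447) or 8 (0.0479) or RIS replicate 4 (0.0499) or 8 (0.0495). The cholesterol list was called without RIS replicate 8 (0.0414) and without the 4 libraries whose deviations rise most with GC (0.043). Over 9 alternatives the adjusted p ranged from 4.05e-07 to 0.245 for the interferon list and from 4.62e-05 to 0.399 for the cholesterol list. In the stress list the serine synthesis genes PHGDH (-2.32, SE 0.0983) and PSAT1 (-2.28, SE 0.105) fell, and its median (0.29) and mean (-0.02) differed in sign. With an estimated correlation the calls of the proliferation, recombination, p53, inflammatory, protease, Notch and RAS and ERK lists held, with adjusted p values from 0.00704 to 0.0485. Adjusted over the list alone, 4 collagen and matrix genes rose and 9 interferon-stimulated genes fell, and the other 14 lists gave the counts above. The highest and lowest genes outside the lists were CYP26B1, a retinoic acid hydroxylase (8.44, SE 0.19), and the oxytocin receptor gene OXTR (-6.56, SE 0.316), NRXN3 (-5.29, SE 0.186), TNFSF4 (-5.19, SE 0.115) and ANKRD1 (-4.96, SE 0.133).

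**Figure D1:**
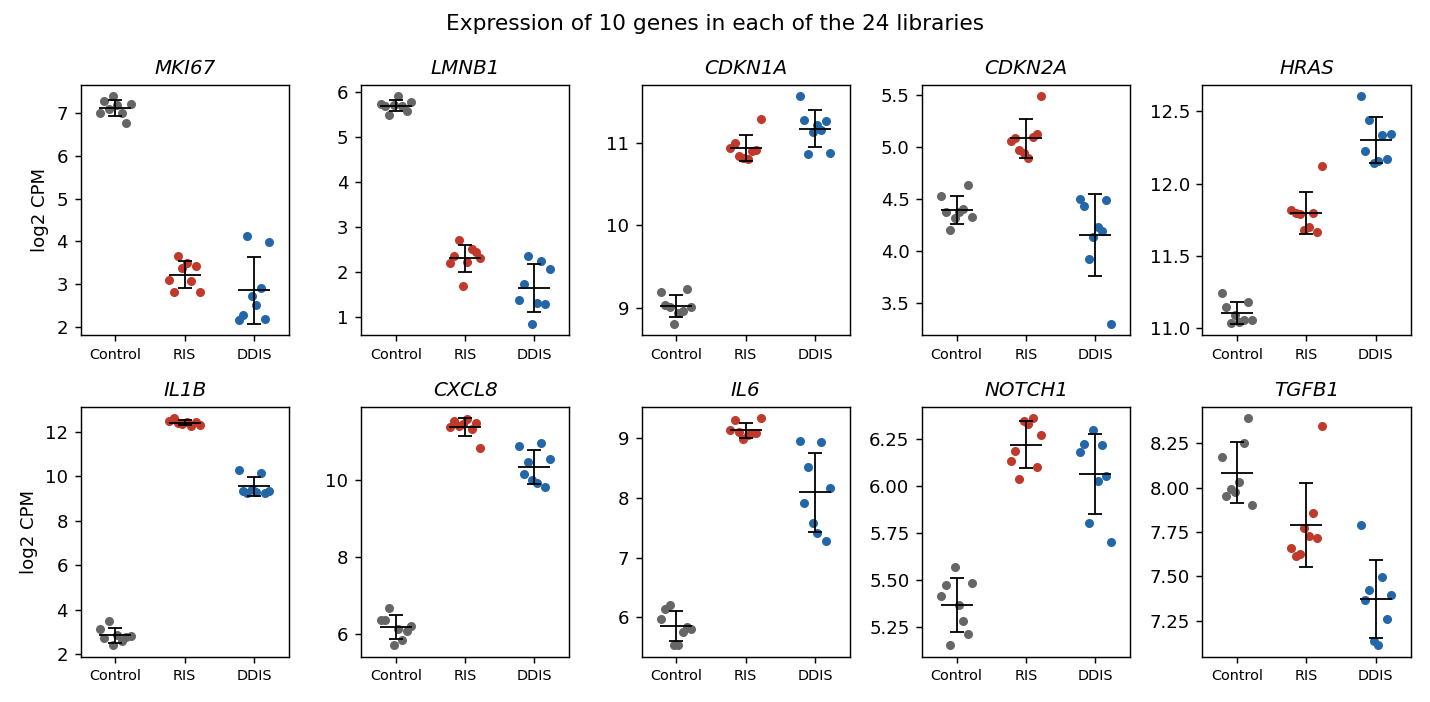
Expression of 10 named genes in each library, as log2 CPM on the vertical axis, for the 8 control, 8 RIS and 8 DDIS libraries on the horizontal axis. Each point is a library, the bar is the mean and the error bar the SD. MKI67 and LMNB1 were lower in both senescent groups, and IL1B averaged 7.12 CPM in control, 5502 CPM in RIS and 781.6 CPM in DDIS.

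The second comparison asks the same of senescence after DNA damage by etoposide. MMP3 rose from 7.67 ± 1.06 to 1225 ± 200 CPM in DDIS (SD, n = 8 each; log2 fold change 7.31, SE 0.122, adjusted p = 2.55e-27), and IL1B from 7.12 ± 1.89 to 781.6 ± 265 CPM (6.77, SE 0.194, adjusted p = 3.09e-20). THBD, thrombomodulin, rose by 7.80 (SE 0.317) from 7 counts in all control libraries together. LMNB1 fell by 4.12 on the log2 scale (SE 0.146), MKI67 by 4.11 (SE 0.231), MYBL2 by 4.02 (SE 0.256) and the mitotic kinesin gene KIFC1, which overlaps a gene on the other strand over 14% of its exonic length, by 3.83 (SE 0.157). CDKN1A rose from 522 ± 48.9 to 2323 ± 366 CPM (2.15, SE 0.0902). In this comparison 7552 of 12596 genes were called, 3831 higher and 3721 lower, of which 1704 changed 2-fold or more (1004 higher, 700 lower), and the groups did not overlap for 30.4% of the genes against 0.0155% by chance. Within the letters A, B and C alone, 4960, 7047 and 4075 genes were called.

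Inflammatory genes rose in DDIS for 22 of 24 members and fell for 2 (median log2 fold change 4.41, adjusted p = 7.19e-16). CSF3 had 2978 counts in DDIS against 3 in control, a ratio of 915 with a 95% counting interval of 313 to 4439, and the chemokine gene CCL20 rose by 7.22 (SE 0.518). CXCL8 rose by 4.21 (SE 0.181), IL1A by 4.66 (SE 0.226) and IL6 by 2.36 (SE 0.213), while CCL2 (-1.45) and CSF1 (-0.22), named for their RIS values, fell. Proteases and inhibitors rose for 18 of 22 and fell for 2 (median 1.37, adjusted p = 3.14e-10), among them TFPI2, a serine protease inhibitor (4.27, SE 0.0874). Of the 19 NF-kB, C/EBP and AP-1 genes 12 rose and 3 fell (median 0.52, adjusted p = 0.0016), with the stress factor ATF3 at 2.91 (SE 0.103), FOSB at 2.91 (SE 0.288) and CEBPB at 1.42 (SE 0.0878). That call was lost with an estimated correlation (adjusted p = 0.184, range 2.24e-10 to 0.184 over 9 alternatives).

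All 39 genes of S phase and mitosis fell (median -2.82, adjusted p = 2.92e-24), as did 22 of 24 genes of homologous recombination and fork repair (median -2.44, adjusted p = 1.38e-12), for example EXO1 (-3.59, SE 0.225) and CLSPN (-3.25, SE 0.194). Of 30 p53 target genes 28 rose and none fell (median 0.93, adjusted p = 9.65e-13), with GDF15 at 3.97 (SE 0.119) and the decoy receptor gene TNFRSF10C at 3.02 (SE 0.233). DDIS replicates 3 and 8 stood apart in these lists. The mean log2 CPM of the S phase and mitosis list was 3.30 in replicate 3, 3.08 in replicate 8, 2.07 to 2.38 in the other 6 DDIS libraries, 2.26 to 2.53 in RIS and 4.98 to 5.35 in control. For recombination genes it was 2.14 and 2.10, against 1.38 to 1.81 in the other 6, and for p53 targets 5.80 and 5.85, against 6.04 to 6.18. MKI67 stood at 17.2 and 15.5 CPM, against 4.14 to 7.17, and MYBL2 at 4.77 and 5.39 CPM, against 0.792 to 1.26. CDKN2B rose by 1.29 (SE 0.118), and CDKN2A did not pass the test (-0.22, SE 0.121, adjusted p = 0.121). It was called lower without the low-count filter (-0.25, adjusted p = 0.0491) and with the GC correction (-0.25, adjusted p = 0.0343), with a range of 0.0343 to 0.552 over 33 alternatives. Senescence hallmark genes rose for 11 of 24 and fell for 8, with HMGB2 at -2.55 (SE 0.193). The list was not called (adjusted p = 0.692), and its median (0.07) and mean (-0.11) differed in sign.

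NOTCH1 rose from 41.2 ± 4.1 to 67.2 ± 9.54 CPM in DDIS (0.71, SE 0.082, adjusted p = 1.52e-08). The Notch list was not called (9 higher, 4 lower of 18, median 0.27, adjusted p = 0.195). MAML3 (1.64, SE 0.138) and HEY1 (1.34, SE 0.129) rose, and JAG1 stood at 0.21 (SE 0.129, adjusted p = 0.17), with a call without DDIS replicate 3 (0.35, adjusted p = 0.00534) or DDIS replicate 8 (0.31, adjusted p = 0.0388), and a range of 0.00534 to 0.381 over 33 alternatives. TGFB1 fell from 272.5 ± 33.6 to 167 ± 26.4 CPM (-0.71, SE 0.101). The TGF-beta list held 9 higher and 13 lower of 27 and was not called (median -0.17, adjusted p = 0.0972, but 0.00031 without the low-count filter, range 1.74e-07 to 0.442 over 9 alternatives), with ACTA2 at -2.39 (SE 0.143) and the tropomyosin gene TPM1 at -1.81 (SE 0.0827). Of 30 collagen and matrix genes 28 fell and none rose (median -1.18, adjusted p = 4.36e-13), for example COL3A1 (-2.24, SE 0.173) and ELN (-2.91, SE 0.149).

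RAS and ERK output genes were higher for 20 of 27 and lower for 4 in DDIS, where no 4-OHT was given (median 0.70, adjusted p = 1.09e-07), with AREG at 4.66 (SE 0.269) and DUSP4 at 4.55 (SE 0.136). HRAS rose to 5079 ± 588 CPM (1.20, SE 0.0727), and NRAS fell by 1.28 (SE 0.0723). Lysosome and autophagy genes rose for 23 of 26 and fell for 1 (median 0.45, adjusted p = 2.68e-07), such as MAP1LC3B (1.20, SE 0.0525) and SQSTM1 (1.41, SE 0.09), which overlaps a gene on the other strand over 22.4% of its exonic length. The call was lost with an estimated correlation (adjusted p = 0.119, range 5.58e-11 to 0.119 over 9 alternatives). Cholesterol synthesis genes fell for 17 of 23 and rose for 1 (median -0.36, adjusted p = 0.00033), the latter TM7SF2 (1.29, SE 0.195), against ACAT2 (-1.21, SE 0.107, with an overlap of 17.2%). This call too was lost (adjusted p = 0.119 with an estimated correlation, range 2.24e-10 to 0.119). Interferon-stimulated genes fell for 10 of 21 and rose for 2 (median -0.28, adjusted p = 0.0451), with OAS3 at -2.39 (SE 0.126) and USP18 at -1.50 (SE 0.123). This call was lost with an estimated correlation (adjusted p = 0.209, range 2.37e-07 to 0.209). It was also lost without DDIS replicate 1 (adjusted p = 0.0743), 2 (0.0601), 4 (0.0515) or 5 (0.0556), without the 4 libraries whose deviations rise most with GC (0.103) and without the 2 libraries with the most counts on unmatched IDs (0.0572). Not called were glycolysis and hypoxia genes (10 higher, 7 lower of 23, adjusted p = 0.29, VEGFA at 1.47 and PFKP at -1.30). Nor were genes of unfolded protein and amino acid stress (8 higher, 7 lower of 21, adjusted p = 0.75, median -0.03 and mean 0.05), whose mean log2 CPM was 6.79 in DDIS replicate 1 and 6.62 to 6.68 in the other 7 DDIS libraries. Among these PHGDH fell by 2.01 (SE 0.0958) and DDIT3, with an overlap of 31.6%, rose by 1.76 (SE 0.102). With the estimated correlation the calls of the proliferation, recombination, p53, inflammatory, protease, collagen and RAS and ERK lists held, with adjusted p values from 0.00948 to 0.0439. Adjusted over the list alone, 24 recombination genes and 9 hallmark genes fell, and the other 14 lists gave the counts above.

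RIS and DDIS shared much of their change against the same 8 control libraries. Of the genes called in both, 5117 moved the same way, 2581 higher and 2536 lower, and 484 the opposite way, 232 of them higher in RIS. Independent lists of these sizes would share 2344 (1173 higher, 1171 lower). Over genes, which are not independent replicates, the log2 fold changes had a correlation of 0.806 and a covariance of 0.782. In 20 fits with simulated unchanged groups against the real controls, no gene was shared. Their correlation averaged 0.0198 (-0.0386 to 0.0766) and their covariance 0.000275. These groups were drawn around the mean of the same control libraries, so the error of that mean was left out. The difference of covariances of 0.782 therefore cannot show how much the shared controls add. With the controls split 4 and 4 between the comparisons, 24 fits shared 4274 genes on average (4179 to 4378), with a correlation of 0.787 and a covariance of 0.781. Within the letters A, B and C, 3164, 4450 and 2416 genes moved the same way.

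**Figure D2:**
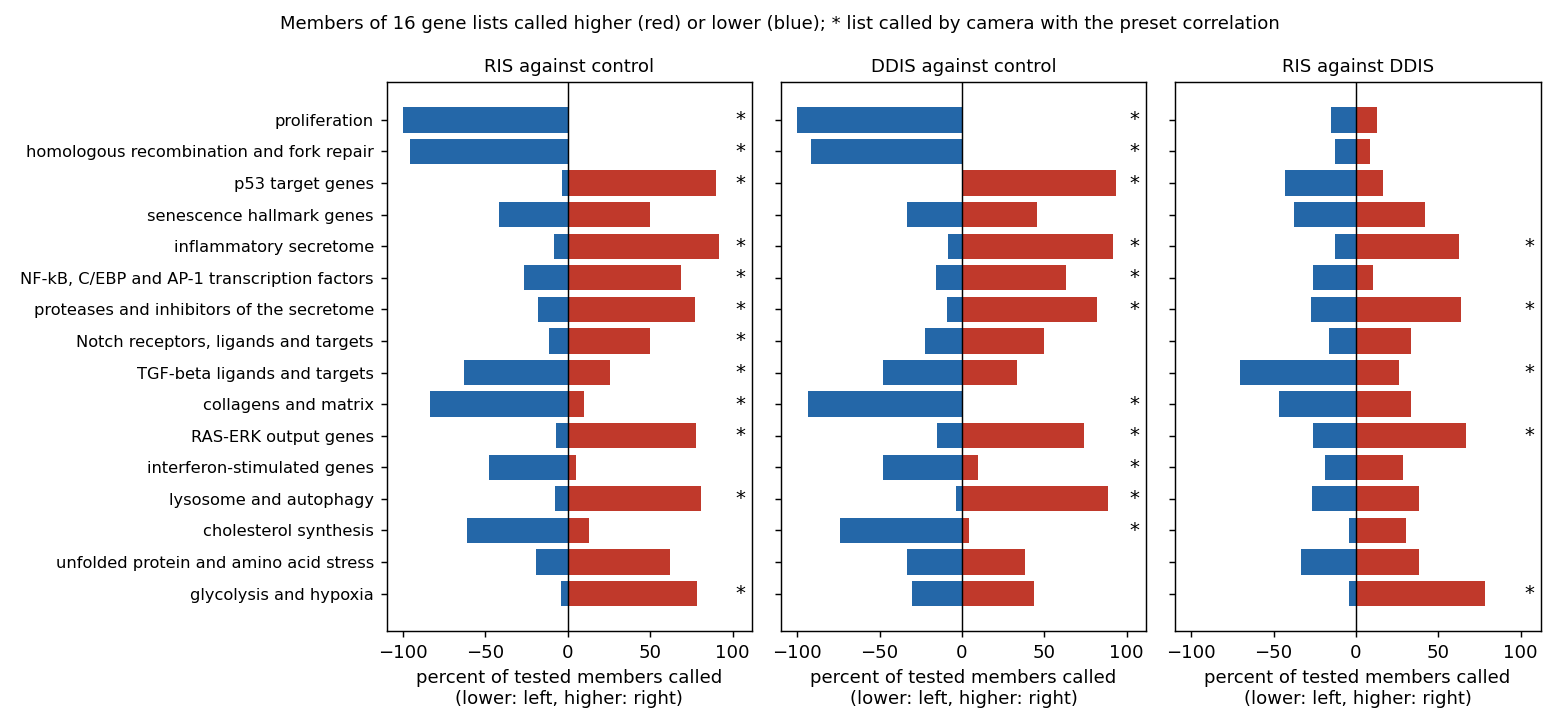
Share of the tested members of 16 gene lists called higher (red, to the right) or lower (blue, to the left), in percent on the horizontal axis, for the 3 comparisons. A star marks a list called by camera with the preset correlation. All 39 genes of S phase and mitosis were lower in RIS and in DDIS, and 22 of 24 inflammatory genes were higher in each.

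The third comparison sets RIS against DDIS directly and asks where the senescent states differ. IL1B was 5502 ± 427 CPM in RIS and 781.6 ± 265 CPM in DDIS (SD, n = 8 each; log2 fold change 2.82, SE 0.15, adjusted p = 1.81e-14). TIE1, an endothelial receptor kinase gene (ENSG00000066056, chromosome 1, 43766653 to 43788779, plus strand), was 29.8 ± 4.81 CPM in RIS and 2.06 ± 0.561 in DDIS (3.84, SE 0.166). ACP5 (3.73, SE 0.144), TNFSF15 (3.39, SE 0.13) and KIF21B (3.17, SE 0.103) followed. GPRC5A, an orphan receptor gene (ENSG00000013588, chromosome 12, 13044493 to 13070871, plus strand), was 1.68 ± 0.374 CPM in RIS and 47.4 ± 8.74 in DDIS (-4.81, SE 0.143). ANKRD1 (-4.74, SE 0.133), the small heat shock protein gene CRYAB (-4.11, SE 0.192, with an overlap of 27.2% on the other strand) and the keratin gene KRT7 (-3.70, SE 0.231) were also lower in RIS. The test called 6745 of 12596 genes, 3305 higher and 3440 lower in RIS, of which 1139 differed 2-fold or more (306 higher, 833 lower), and the groups did not overlap for 18.4% of the genes against 0.0155% by chance. Within the letters A, B and C alone, 3243, 6389 and 3328 genes were called.

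Inflammatory genes were higher in RIS for 15 of 24 and lower for 3 (median 0.66, adjusted p = 0.000744), a call lost with an estimated correlation (adjusted p = 0.545). IL1A stood at 1.81 (SE 0.144), CXCL8 at 0.99 (SE 0.158) and IL6 at 0.91 (SE 0.199). The DDIS libraries were not alike in this list. Its mean log2 CPM was 6.62 in DDIS replicate 1 and 6.77 in DDIS replicate 6, inside the RIS range of 6.58 to 7.00, and 5.70 to 6.03 in the other 6 DDIS libraries. Proteases and inhibitors were higher for 14 of 22 and lower for 6 (median 0.56, adjusted p = 0.00316), a call lost with an estimated correlation (adjusted p = 0.315) and with the GC correction (adjusted p = 0.0638). SERPINB2 stood at 1.93 (SE 0.0862). RAS and ERK output genes were higher for 18 of 27 and lower for 7 (median 0.72, adjusted p = 5.1e-05), with the cytokine gene LIF at 1.89 (SE 0.167), and lost the call with an estimated correlation (adjusted p = 0.142). Glycolysis and hypoxia genes were higher for 18 of 23 and lower for 1 (median 0.58, adjusted p = 1.76e-07), with neuronal enolase, ENO2, at 1.62 (SE 0.0794), and lost the call likewise (adjusted p = 0.315 with an estimated correlation). TGF-beta ligands and targets were higher for 7 of 27 and lower for 19 (median -0.34, adjusted p = 0.00316), with calponin, CNN1, at -2.10 (SE 0.133), and this call too was lost (adjusted p = 0.386 with an estimated correlation). These estimated-correlation values were the highest of 9 alternatives for each list, and the lowest were 1.15e-07, 4.73e-09, 5.03e-13, 3.69e-17 and 5.95e-09 in the same order.

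The other 11 lists were not called in RIS against DDIS. NOTCH1 did not differ detectably (0.15, SE 0.08, adjusted p = 0.118), except without the low-count filter (0.21, adjusted p = 0.0437) and without DDIS replicate 4 (0.20, adjusted p = 0.0391), with a range of 0.0391 to 0.474 over 33 alternatives. Notch genes were higher in RIS for 6 of 18 and lower for 3 (adjusted p = 0.323), with the Notch target HES1 at 1.36 (SE 0.0944). S phase and mitosis genes were higher for 5 of 39 and lower for 6 (adjusted p = 0.942, the median of -0.20 opposite in sign to the test's direction). Their mean log2 CPM in DDIS replicates 3 (3.30) and 8 (3.08) lay above the RIS range of 2.26 to 2.53. In this list CENPE (-1.37, SE 0.579, adjusted p = 0.0495) lost its call with the letter block, another scaling, no filter, limma voom, the GC correction and without the 2 libraries with the most counts on unmatched IDs. It also lost it in 12 of the fits without single libraries (RIS 1, 2, 3, 4, 6 or 8, DDIS 2, 3, 4, 5, 6 or 8), where the lost calls had adjusted p values from 0.0514 to 0.0957. Over all 33 alternatives they ranged from 0.00829 to 0.183. Recombination genes were higher for 2 of 24 and lower for 3 (adjusted p = 0.853, BRIP1 at -0.92). The p53 targets were higher for 5 of 30 and lower for 13 (adjusted p = 0.232, TNFRSF10C at -1.39), and hallmark genes were higher for 10 of 24 and lower for 9 (adjusted p = 0.731, median -0.04 against an upward test, IGFBP3 at -1.48). NF-kB, C/EBP and AP-1 genes were higher for 2 of 19 and lower for 5 (adjusted p = 0.458), with ATF3 at -1.89 (SE 0.0945). Collagen and matrix genes were higher for 10 of 30 and lower for 14 (adjusted p = 0.731), with decorin, DCN, at -1.92 (SE 0.131). Interferon-stimulated genes were higher for 6 of 21 and lower for 4 (adjusted p = 0.933, mean -0.05 against an upward test, USP18 at 1.17), and lysosome genes higher for 10 of 26 and lower for 7 (adjusted p = 0.323, GABARAPL1 at -1.09). Cholesterol synthesis genes were higher for 7 of 23 and lower for 1 (adjusted p = 0.103, INSIG1 at 0.98) and stress genes higher for 8 of 21 and lower for 7 (adjusted p = 0.933, PSAT1 at -1.36). Without the low-count filter the hallmark, lysosome and cholesterol lists were called (adjusted p = 0.0442, 0.00105 and 3.03e-05, with ranges of 0.00633 to 0.908, 0.00105 to 0.908 and 3.03e-05 to 0.679 over 9 alternatives). Adjusted over the list alone, 4 proliferation genes were lower, 14 p53 targets lower, 16 inflammatory genes higher, 20 TGF-beta genes lower, 11 lysosome genes higher, and 3 interferon-stimulated genes were higher and 3 lower, with the other 10 lists as above.

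Of the other anchor genes, CDKN2B (1.36, SE 0.108), CDKN2A (0.91, SE 0.118), NRAS (0.77, SE 0.0724), LMNB1 (0.64, SE 0.185) and TGFB1 (0.42, SE 0.101) were higher in RIS than in DDIS, and HRAS (-0.51, SE 0.0719) was lower. CDKN1A was lower in RIS (-0.24, SE 0.0864, adjusted p = 0.0216), a call lost without DDIS replicate 1 (adjusted p = 0.061), 2 (0.0604), 5 (0.052) or 7 (0.0585), with a range of 0.000191 to 0.061 over 33 alternatives. MKI67 (0.20, SE 0.26, with 17.2 and 15.5 CPM in DDIS replicates 3 and 8 and 4.14 to 7.17 in the other 6), CEBPB (-0.03, SE 0.0846) and JAG1 (-0.15, SE 0.129) did not pass the test, with JAG1 called without DDIS replicate 3 (-0.28, adjusted p = 0.0263, range 0.0263 to 0.61).

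Markers of cell types were looked up beside these changes, with levels as CPM of all gene counts without TMM scaling, and those named here were chosen after their values were seen. Of 12 fibroblast markers 10 fell in RIS and none rose, and in DDIS 9 fell and 1 rose, the transcription factor gene TCF21 (1.36, SE 0.0736). The median control level of fibroblast markers was 332 CPM. Smooth muscle and pericyte markers (8 tested) rose for 2 and fell for 6 in RIS, and rose for 2 and fell for 4 in DDIS, RGS5 rising in both (3.58 and 4.17). Epithelial markers (5 tested, median control level 0.451 CPM over all 12) fell for 5 in RIS and for 2 in DDIS, namely KRT8 (-1.34) and KRT18 (-0.72). Of 3 endothelial markers tested, TIE1 (3.47, SE 0.161) and VWF (1.18, SE 0.177) rose and TEK fell (-0.47) in RIS, and VWF rose in DDIS (1.03). Of 3 leukocyte markers tested, CD68 and CSF1R rose and CORO1A fell in each senescent group, and CD68, a lysosomal protein that many cell types express, went from 42.7 ± 4.12 CPM in control to 113.7 ± 7.14 in RIS and 160.5 ± 24.7 in DDIS. All other endothelial and leukocyte markers stayed under 2 CPM on average in every group.

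Libraries of DDIS also differed from the others in how many genes they detected. At an equal depth, 20340 ± 696 genes had a count in DDIS, 17173 ± 222 in control and 17166 ± 250 in RIS (SD, n = 8 each). The 8 DDIS libraries all lay above every control library (exact two-sided permutation p = 0.0001554, the smallest this test can give, adjusted p = 0.000544 over 21 comparisons). Reads outside annotated genes made up 7.76% ± 0.93 in DDIS and 6.08% ± 1.12 in control (exact permutation p = 0.00824, adjusted p = 0.0157), and long noncoding RNA 0.55% ± 0.0765 and 0.372% ± 0.0379 of gene counts (exact permutation p = 0.0003108, adjusted p = 0.000725). Mitochondrial transcripts took 2.27% ± 0.196 of gene counts in control, 2.88% ± 0.258 in RIS (exact permutation p = 0.0004662) and 2.97% ± 0.295 in DDIS (exact permutation p = 0.0003108).

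**Figure D3:**
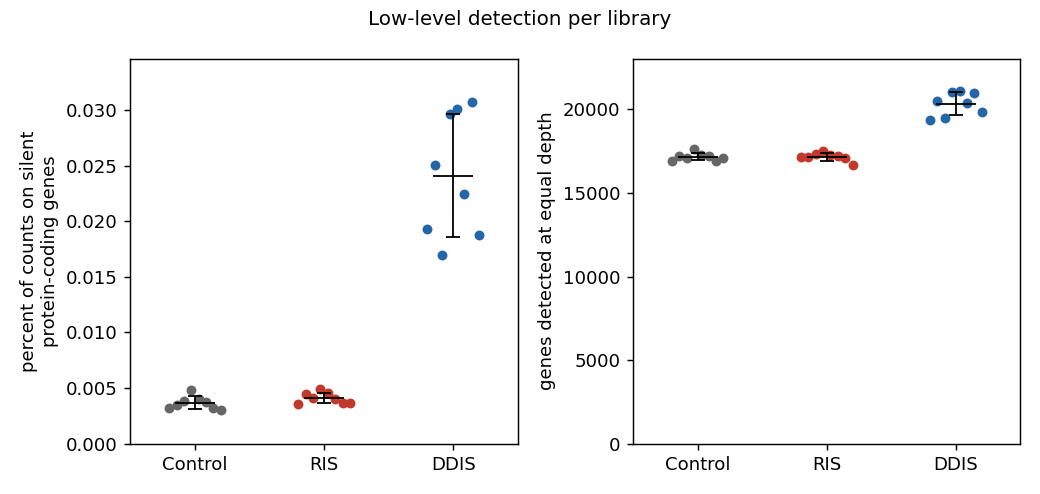
Share of gene counts on silent protein-coding genes (mean under 0.1 CPM over the 24 libraries), in percent (left), and number of genes detected at equal depth (right), for each of the 24 libraries by group. Points are libraries, bars the mean and error bars the SD. The DDIS libraries lie above all control and RIS libraries in both panels, with means of 0.0241% and 20340 genes.

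Within each group, the mean log2 CPM of the Notch list, of the TGF-beta list and of CEBPB was set against that of the inflammatory list over the 8 libraries (9 relations, exact two-sided permutation of the pairings). None passed adjustment. Notch against inflammatory genes in RIS had r = -0.136 (exact p = 0.743, adjusted 0.834) and rho = -0.19 (exact p = 0.665), with r = 0.522 without the 2 libraries farthest in the Notch score and r = -0.382 with the letters' means removed. TGF-beta against inflammatory genes in DDIS had rho = 0.881 (exact p = 0.00724, adjusted p = 0.0652) and r = 0.658 (exact p = 0.0623, adjusted 0.187), with r = 0.436 without the 2 farthest libraries and r = 0.724 with the letters' means removed. With each library's GC trend regressed out, added after the data were seen, r was 0.18 (exact p = 0.81). CEBPB against inflammatory genes in DDIS had r = 0.816 (exact p = 0.0262, adjusted 0.179) and rho = 0.5 (exact p = 0.216), with r = 0.871 with the letters' means removed and 0.599 with the GC trend regressed out. It rested on DDIS replicates 1 and 6, without which r was -0.132. In RIS, TGF-beta against inflammatory genes had r = -0.235 (exact p = 0.562) and rho = -0.381 (exact p = 0.36), with r = -0.530 without the 2 farthest and -0.623 with the letters' means removed, opposite in sign to DDIS. In control it had r = 0.760 (exact p = 0.0398, adjusted 0.179) and rho = 0.619 (exact p = 0.115), with 0.659 and 0.218 in the same order. CEBPB in RIS had r = -0.453 (exact p = 0.267) and rho = 0.0714 (exact p = 0.882), with 0.634 and -0.387, and in control r = -0.163 (exact p = 0.71) and rho = -0.381 (exact p = 0.36), with -0.0780 and 0.407. Notch genes in DDIS had r = 0.606 (exact p = 0.115) and rho = 0.310 (exact p = 0.462), with 0.541 and 0.613, and in control r = 0.0866 (exact p = 0.834) and rho = 0.190 (exact p = 0.665), with 0.336 and 0.550. Differences of these relations between groups were not tested.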

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

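The test of sequencing depth was chosen after the depths and the GC correlations of the libraries had been seen, the letter test was replaced after its first value had been seen, the tests of the fold of silent genes over 100 kb from expressed ones and of olfactory receptor genes were added after their counts had been seen, list scores other than those of the Notch, TGF-beta and inflammatory lists were tested after they had been seen, and the criteria for the GC test were amended after its value had been seen.

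Other splits of the same 16 libraries into 8 and 8 were fitted, 100 per comparison with the real one included. For RIS against control, 1 of 100 splits, the real one, called as many as 7821 genes, and the highest of the others called 548. For DDIS against control it was again 1 of 100, with 7552 genes in the real split and 5375 in the highest other, which kept 7 of the 8 libraries of each group together. For RIS against DDIS it was 1 of 100, with 6745 and 974. Among the splits drawn, a random assignment of these libraries to groups thus never gave the real counts. The splits take the library as the unit, and the labels do not give cultures or days. They therefore cannot exclude chance differences between cultures or days.

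For each named gene and each measure, the gap between the most distant of the 8 libraries of a group and its neighbour was divided by the range of the group. This ratio passed Dixon's critical value for 22 of 237 sets of 8 libraries (79 genes, 3 groups), where chance gives about 1 in 20. RIS replicate 8 accounted for 16 of them. It was the highest of its group for GDF15 (0.780), SQSTM1 (0.6701), HRAS (0.666), TGFB1 (0.666), TM7SF2 (0.629), CDKN2A (0.615), NEU1 (0.601), CDKN1A (0.596), CEBPB (0.577), FBLN1 (0.554) and CRYAB (0.554). It was the lowest for IL1A (0.668), NRAS (0.654), CXCL8 (0.637), TNFSF4 (0.627) and CXCL10 (0.530). Control replicate 7 was the lowest of its group for CLSPN (0.680) and BARD1 (0.640), and DDIS replicate 1 for OXTR (0.566). DDIS replicate 6 was the highest for IL1A (0.585) and the lowest for USP18 (0.565), and Control replicate 4 the lowest for KIF21B (0.617).

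The 4 libraries whose deviations from their groups rose most with the GC content of genes were picked for that rise. They were RIS replicate 8, DDIS replicate 1, Control replicate 7 and Control replicate 1 (rank correlations of 0.750, 0.705, 0.514 and 0.470). They deviated in the same genes, with a mean correlation of deviations of 0.552 over 6 pairs. The choice by GC content can itself raise this correlation, so the correlation is not independent of the GC trend. Taking each library's GC trend out left a mean correlation of 0.338, above 0.5 times its former value, the bound set before the result was seen, but the pairs ranged from 0.157 to 0.518 and 2 of 6 fell under 0.5 times their own former value, so a GC bias stays open as the whole cause. A batch marked by the letter of the file codes stays open as well. The 4 pairs of different letters correlated at 0.554 on average (0.353 to 0.759) and the same-letter pairs at 0.55. The lowest lay above 0.5 times the same-letter mean, the bound set against such a batch. The choice of libraries by GC content can raise both kinds of pair, so this comparison cannot decide. A first test passed its bound of 0.1, with correlations of -0.135 to other same-letter libraries and -0.238 to the rest (difference 0.103, one-sided permutation p = 0.0418). Depth stays open too, with a Spearman correlation of -0.398 between the GC rank correlation and the total count of the 24 libraries (permutation p = 0.0546), under the 0.5 set for a cause and over the 0.3 set against it. No biological explanation was tested, and these libraries belong to 3 groups. Control replicate 1 and DDIS replicate 1 share a replicate number and the file code A1. Control replicate 7 and RIS replicate 8 share the letter C. Whether such pairs shared a culture or handling is not given in the labels.

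Silent protein-coding genes, 4355 with a mean under 0.1 CPM over the 24 libraries, took 0.0241% of gene counts in DDIS, 0.00368% in control and 0.00411% in RIS (exact two-sided permutation p = 0.0001554 for DDIS against control, the smallest possible, and 0.136 for RIS), and reads outside annotated genes took 7.76% in DDIS, while 2641 of the silent genes had more counts in DDIS than in control and 159 fewer. The intervals below resample genes and hold no spread between libraries. The tables argue against fewer counts on abundant genes as the whole cause of the additional genes detected. The gap at equal depth, DDIS mean minus control mean, was 3168 genes with all genes and 2967 without the 100 most abundant. Genomic DNA would raise silent genes alike. Olfactory receptor genes gained 0.134 times the counts per kilobase of other silent genes (95% interval 0.0906 to 0.192), under the bound set against DNA as the whole source. But the annotation release of the counting is not given, so the lengths used may not be those counted. In DDIS, olfactory receptor genes had 4.11 times their control counts per kilobase (29 counts in control and 117 in DDIS, 95% interval 2.63 to 7.58). Other silent genes had 6.63 times, inside that interval. The test therefore cannot exclude DNA as the source. An expressed neighbour was a gene with a mean of at least 5 CPM. Reads running in from such genes within 100 kb cannot be the whole cause. Silent genes over 100 kb from an expressed gene had 6.73 times the counts per kilobase of control in DDIS (95% interval 5.85 to 7.79). Genes under 5 CPM or without a known position were not counted as neighbours, so reads running in from them stay open. Reads from expressed neighbours stay open for a part of the gain. Silent genes within 10 kb of one gained 1.90 times as much as those over 100 kb away (1.69 to 2.13, between the bounds of 1.5 and 2). Wider transcription after etoposide also stays open and was not tested.

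Among 24 sets of library measures 6 passed the same value. Control replicate 6 had the highest share of its group for reads outside genes (8.50%, ratio 0.531) and for counts on IDs without a match in the annotation (5.57%, 0.906), and the lowest for protein-coding genes (92.5%, 0.912). RIS replicate 2 had the highest share on unmatched IDs (5.01%, 0.784) and the lowest on protein-coding genes (92.9%, 0.810). Control replicate 4 had the highest share of long noncoding RNA (0.453%, 0.591). Among 48 sets of list scores (mean log2 CPM of 16 lists in 3 groups) 3 passed. RIS replicate 8 was the highest of its group for lysosome and autophagy genes (7.27, ratio 0.701) and the lowest for recombination genes (1.04, 0.603), and DDIS replicate 1 the highest for genes of unfolded protein and amino acid stress (6.79, 0.660).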

How the results depend on the processing

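The GC correction and the fits without the 4 libraries that deviate with GC content and without the 2 libraries with the most counts on unmatched IDs were chosen after the data were seen.

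Counts are given for RIS against control, DDIS against control, RIS against DDIS and the genes called the same way in both senescent states, in that order. The values with all settings as reported were 7821, 7552, 6745 and 5117. Within letter A alone they were 5090, 4960, 3243 and 3164, and within letter C alone 4477, 4075, 3328 and 2416, with 3 libraries per group in place of 8. Letter B alone, with 2 libraries per group, gave 7082, 7047, 6389 and 4450, so the number of libraries alone does not order these counts. A 2-fold minimum left 2174, 1704, 1139 and 1194 by construction. Leaving out 1 library at a time gave 7622 to 8124, 7354 to 8154, 6397 to 7259 and 4949 to 5469. A block for the replicate number gave 7866, 7638, 6791 and 5151, and changed no named gene and no list other than the interferon-stimulated genes in RIS against control (adjusted p = 0.0462). The values do not settle whether the numbers pair the libraries. Same-numbered libraries deviated together (correlation over 0.1) for 3, 6 and 4 of 8 pairs in the 3 comparisons. Of 8 libraries, 2, 3 and 3 correlated best with their own number, where chance gives about 1 of 8. Same-number correlations ranged from -0.483 in RIS against control to 0.503 in DDIS against control. The GC correction gave 8320, 8275, 7441 and 5582, the fits without the 4 libraries 8410, 8254, 7654 and 5532, and those without the 2 libraries 7403, 7433, 6470 and 4932. Without a count filter, with 32082 genes tested, the counts were 8321, 10477, 9339 and 5193, the share of higher genes among those called in DDIS against control was 61.9% in place of 50.7%, and the median log2 fold change of all genes was 0.39 in place of 0.00. In RIS against DDIS that share was 39.8% in place of 49.0% (median -0.40 in place of -0.02), and 43.2% with upper quartile scaling (2909 higher, 3826 lower). Leaving out 1 library moved it between 43.1% and 51.7%, and moved the share in DDIS against control between 50.4% and 56.9%. With only the groups compared, the share in DDIS against control was 56.6% (4327 higher, 3318 lower). The near-even balance of that comparison thus depends on the libraries and genes in the fit. The filter meant to be stricter kept 13509 genes, more than the 12596 of the reported fit.

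Named genes and lists were not examined with each letter alone, upper quartile scaling, the filter meant to be stricter or only the groups compared. Lists were also not examined with DESeq2 or limma voom. In the other alternatives, none of the 137 named-gene results and 48 list results that was called as reported or in the alternative changed direction. Of those not called, CEBPB in RIS against DDIS and 7 of 20 lists changed direction in at least 1 alternative (lowest adjusted p there 0.732 and 0.345), among them S phase and mitosis genes in RIS against DDIS with fry (0.914). DESeq2 changed no named-gene call, and limma voom, the letter block and the other size factors changed 1 each, that of CENPE in RIS against DDIS. Without a filter 6 lists gained a call and none lost it. They are interferon-stimulated genes and cholesterol synthesis in RIS against control (adjusted p = 0.0347 and 0.00946), TGF-beta genes in DDIS against control (0.00031) and hallmark genes, lysosome genes and cholesterol synthesis in RIS against DDIS (0.0442, 0.00105 and 3.03e-05). With an estimated correlation 14 lists lost the call, and fry, which compares a list with no other genes, called 12 lists more. The cause of these changes was not tested. At these depths 1 count is worth 0.12 to 0.22 CPM, which limits genes near the floor such as CSF3 and THBD in control.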

Other observations

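All the gene families named here were chosen and tested after the data were seen, 14 per comparison, and several genes of the muscle and retinoid families were among those whose opposite changes led to them. The void bound for the small RNA test was also set after its value was seen, and the tests of the histone explanations were written before.

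Genes of muscle sarcomeres and contraction fell in RIS. Of 14 tested, 13 fell in RIS and none rose (median log2 fold change -2.43, adjusted p = 4.82e-07, and 0.000473 with an estimated correlation), while in DDIS 6 rose and 7 fell (adjusted p = 0.844). In RIS against DDIS 13 were lower and none higher (median -2.87, adjusted p = 9.15e-11, and 3.13e-05 with an estimated correlation). Those p-values partly restate what led to the family. Without the 6 tested members seen before, 7 of the other 8 fell in RIS (median -3.18, adjusted p = 0.000178, and 0.00283 with an estimated correlation) and 7 were lower in RIS than in DDIS (median -1.91, adjusted p = 7.19e-05, and 0.00293). In DDIS 6 of these 8 fell and 1 rose (median -0.69, adjusted p = 0.0317, and 0.124 with an estimated correlation). Of the 484 genes that moved in opposite directions against control, 22 changed 2-fold or more in each comparison, 20 of them lower in RIS. These include MYPN, a sarcomere protein gene (-1.81 in RIS, 1.77 in DDIS), the smooth muscle myosin gene MYH11 (-1.56 and 1.36), the transcription factor gene KLF4 (-2.68 and 1.79), the growth factor gene FGF7 (-1.59 and 1.34), and CRABP2 (-2.01 and 1.49) and DHRS3 (-1.44 and 1.88), which act in retinoid handling. LDB2 and CCN4 went the other way, LDB2 from 17.5 CPM in control to 37.7 in RIS and 8.43 in DDIS. Retinoid genes as a family held 5 that rose and 2 that fell of 10 in DDIS (adjusted p = 0.048, but 0.41 with an estimated correlation), and 2 and 2 of 7 without the 3 members seen before (adjusted p = 0.654).

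Cytosolic ribosomal protein genes fell in DDIS for 70 of 79 and rose for 1, by little (median -0.37, adjusted p = 8e-13), and 73 were higher and 1 lower in RIS than in DDIS (median 0.39, adjusted p = 1.18e-16). Both calls were lost with an estimated correlation (adjusted p = 0.525 and 0.306), and in RIS against control the family was not called (adjusted p = 0.986). These directions, and those of the muscle and histone genes, held under the other scalings and the GC correction, whereas the ribosomal median in RIS against control changed sign with upper quartile scaling. Of 18 cytosolic tRNA synthetase genes 13 fell and 1 rose in DDIS (median -0.26, adjusted p = 0.00788, and 0.213 with an estimated correlation). Mitochondrially encoded genes rose for 11 of 13 in RIS (median 0.33, adjusted p = 0.0172) and 8 of 13 in DDIS (median 0.42, adjusted p = 0.038), and tubulin genes fell for 7 of 12 in RIS (1 rose, adjusted p = 0.0411) and 8 of 12 in DDIS (3 rose, adjusted p = 0.038). These 4 calls were lost with an estimated correlation (adjusted p from 0.766 to 0.967).

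Histone genes rose in both states although all 39 genes of S phase and mitosis fell. The family held 37 genes. Of 13 tested, 10 rose and none fell in RIS (median 1.67, adjusted p = 0.000178, and 0.0737 with an estimated correlation), 12 rose and none fell in DDIS (median 2.41, adjusted p = 1.11e-09, and 0.00479), and 11 were lower in RIS than in DDIS (median -0.71, adjusted p = 2.92e-05, and 0.0463). H2AC6 went from 22.1 ± 2.54 CPM in control to 70.5 ± 4.64 in RIS and 113.8 ± 7.24 in DDIS, and H4C8 from 2.25 ± 0.798 to 11.5 ± 1.51 and 27.0 ± 4.8 (SD, n = 8 each). H1-10 did not pass the test in any comparison. Many histone messages lack a poly(A) tail, and carry-over of untailed RNA stays open. The median log2 fold change of 6 small RNA genes in DDIS was -0.022 (-0.82 to 0.17), but 5 of them held only 101 to 315 counts over all libraries. The sixth, RN7SK, had most of its control counts in Control replicate 6 and was 2.44 times higher in DDIS than in the other control libraries. A shift over the range of exonic length of the tested histone genes, 493 to 2881 bases, was argued against by 1875 other genes in that range, with a median of 0.042 (0.01 to 0.07). A shift confined to the shortest genes was not tested. Tailed histone messages in arrested cells may also account for the pattern, as a hypothesis that was not tested.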
